A study of Mus musculus with 12 samples.

How the data were processed

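Expression was measured on 12 Affymetrix Mouse Gene 1.0 ST arrays, a platform whose short oligonucleotide probes lie along each transcript and are summarised into 1 value per transcript cluster, called a probe set here. Per the sample titles, 3 arrays each are named miNSC1, miNSC2, WT.NSC and WT.MEFs, called iNSC1, iNSC2, NSC and MEF here. In these names iNSC stands for induced neural stem cells, NSC for neural stem cells and MEF for mouse embryonic fibroblasts. Per the labels' protocols, the iNSC and NSC cultures were kept in medium with 20 ng/ml EGF, 20 ng/ml FGF-2 and 2 µg/ml heparin, and the fibroblasts in DMEM with 10% fetal bovine serum, so cell type and medium differ together wherever the fibroblasts are compared. Cells were washed in medium without serum before collection, RNA was extracted with Trizol and purified on RNeasy columns, and 300 ng of total RNA was labelled with biotin, per the same protocols. The labels do not say what distinguishes iNSC1 from iNSC2, nor whether the arrays of a set come from separate cultures, so every p below measures the spread between these arrays.

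The main table holds log2 values that the authors made by RMA, which corrects background, normalises quantiles and summarises probes, run in Affymetrix Power Tools per the submitters' processing notes. Software versions, the genome build and the annotation release are not given in the sources used here. A second deposited table gives, per the file headers, per-array log2 intensities, a log2 ratio of group means for each of 4 comparisons, and the adjusted and unadjusted p-value of each ratio; the test behind those p-values is not stated. Of its 12 per-array columns, 9 were matched to a sample title and equalled the main table exactly (largest difference 0); the names of the other 3 columns do not match a title and those columns were not used. In that table the ratio for iNSC1 against iNSC2 holds whole numbers only (0 entries were not whole), so it was rounded by the authors and no count at a fold minimum was taken from it.

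There are 28815 probe sets in the main table, of which 21774 are also in the second one. Tested on both groups of probe sets, the second table holds those whose highest mean among the 6 iNSC arrays, the NSC arrays and the MEF arrays is above 3 on the log2 scale: the lowest such value among listed probe sets was 3.0003 and the highest among the 7041 unlisted ones 2.9998. The second table is the source of gene symbols, so the genes tested are those that passed a bound on group means. Of the listed probe sets, 18403 carried 1 gene symbol, 1452 several and 1919 none. Symbols were updated through the Entrez identifier, which matched 17520 of the 18403; 883 kept the name in the table and 3400 symbols changed. Where several probe sets named a gene (706 genes), the probe set with the highest mean over the 12 arrays was kept, which left 17103 genes. No filter on low values was applied, because the arrays carry no detection call; levels are compared within a probe set and never between probe sets.

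Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean for each of the 4 groups and 1 spread shared by all 12 arrays, moderated with a trend on expression (residual degrees of freedom 8, prior degrees of freedom 8.7). The main comparisons were the mean of both iNSC sets minus MEF, the same mean minus NSC, NSC minus MEF, and iNSC1 minus iNSC2; each iNSC set was also set against MEF and NSC on its own. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 17103 genes together with a change of at least 2-fold. All tests were two-sided. The position of the iNSC arrays was described by the slope through 0 of iNSC minus MEF on NSC minus MEF, by root mean square log2 distances, and by a fixed classification of the genes called in NSC minus MEF. Because these comparisons share arrays, unchanged groups were simulated 100 times with the arrays shared in the same way.

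The groups, comparisons, thresholds, 23 gene lists and the rule for named genes were fixed before the data were examined. The rule takes, for each comparison, the 10 genes with the largest rise and the 10 with the largest fall among called genes whose groups do not overlap array by array, without gene models lacking a proper name; the 4 members with the largest change from each list with a call; and a fixed set of 18 marker genes. A gene named outside the rule is said to have been chosen after its values were seen. Lists were tested with camera at a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 23 lists within a comparison, and again with a correlation estimated for each list. fry served as an alternative; it tests whether a list moves on balance in a given direction and does not set the list against other genes.

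Alternatives were an adjusted p with no fold minimum, a minimum of 6 on the log2 scale for the highest group mean, the mean of a gene's probe sets, every probe set on its own, arrays centred on the median, quantile normalisation, moderation without a trend or with robust weights, array weights, only the arrays of the groups compared, the replicate number as a block, the iNSC set as a random block (duplicateCorrelation with statmod 1.5.0), the authors' own ratios and p-values, and leaving out each array in turn. The per-array values of the second table were not run as an alternative because they equal the main table. Gene Ontology terms of 10 to 500 genes were tested after the data had been seen, as were a second list of p53 targets, a second list of macrophage genes and a list of germ line genes. The fit was tested on simulated data with 200 changed genes per comparison: at a change of 1.5 on the log2 scale it recovered 99% to 100% of them, at 2 and 3 it recovered 100%, and it made 0 or 1 false calls among 17103 genes. The list test was also tested on simulated data, where 1 of 39 unshifted lists had a p under 0.05. The simulated genes varied independently, so this does not test the preset correlation for lists whose genes move together. Probe sets with several symbols or none were kept out of all comparisons, and their counts are given among the closing observations. The number of arrays, 3 per group, limits the precision; the median within-group SD was 0.150 on the log2 scale.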

Results

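The series compares expression in mouse cells labelled as induced neural stem cells (iNSC), wild-type neural stem cells (NSC) and wild-type mouse embryonic fibroblasts (MEF). There were 12 arrays in 4 groups of 3: iNSC1 (replicates 1, 2 and 3), iNSC2 (replicates 1, 2 and 3), NSC (replicates 1, 2 and 3) and MEF (replicates 1, 3 and 5). All values are log2 RMA values, and array medians over all probe sets lay between 4.31 and 4.44. Arrays of the same group correlated at 0.987 to 0.994 across genes, and iNSC1 with iNSC2 arrays at a median of 0.9896. Median correlations of NSC arrays were 0.942 with iNSC1 and 0.943 with iNSC2. MEF arrays correlated at medians of 0.839 with iNSC1, 0.846 with iNSC2 and 0.849 with NSC. Genes are not independent replicates, so these values describe the arrays and carry no p.

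The markers fixed for neural stem cells were mixed between the NSC-labelled and MEF arrays, whereas 25 of 27 fibroblast markers were lower in the NSC-labelled arrays. Of 21 neural stem cell markers, 2 were called higher and 2 lower in the NSC-labelled arrays, and 8 were higher and 5 lower at an unadjusted p under 0.05. Sox2, a transcription factor of neural and pluripotent stem cells, read 4.56 ± 0.057 in iNSC1, 4.42 ± 0.091 in iNSC2, 4.58 ± 0.12 in NSC and 4.502 ± 0.046 in MEF (SD, n = 3 arrays each). Its NSC minus MEF difference was 0.077 (95% confidence interval -0.15 to 0.31). Nes, the intermediate filament nestin of neural progenitors, read 4.79 ± 0.30 in NSC against 5.15 ± 0.29 in MEF (SD, n = 3). Fabp7, a lipid carrier of radial glia, differed by 0.12 (-0.14 to 0.38) and Gfap, the astrocyte filament also found in neural stem cells, by 0.13 (-0.22 to 0.48). Sox1 was 1.02 ± 0.087 higher (SE) in the NSC than in the MEF arrays, a call that ended without MEF replicate 1 (0.94), and Pax6 was 1.16 ± 0.14 higher. Olig2, a factor of oligodendrocytes and some neural progenitors, was 1.11 ± 0.13 higher, while Msi1 (0.70 ± 0.13) and Sox21 (0.97 ± 0.13; named after its value was seen) read higher without reaching 2-fold.

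Pou5f1, the POU-domain transcription factor of pluripotent cells and germ cells, read 12.98 ± 0.025 in iNSC1, 13.01 ± 0.033 in iNSC2 and 12.89 ± 0.020 in NSC against 3.55 ± 0.26 in MEF (SD, n = 3 each). The authors' table places it on chromosome 17 from 35642996 to 35647714, plus strand, in a genome build that is not given in the sources used here. The probe set for Nanog also names Nanogpd and was not tested. Its group means ran from 3.81 in NSC to 4.21 in MEF. Col1a1, a chain of fibrillar collagen, read 12.25 ± 0.025 in MEF and 5.604 ± 0.083 in NSC, and Thy1, a surface antigen of fibroblasts, 11.01 ± 0.076 and 5.50 ± 0.36 (SD, n = 3). Because of these readings, groups are called NSC-labelled and iNSC-labelled here, and every direction below is a difference between arrays with those labels, not between known cell types.

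**Figure D1:**
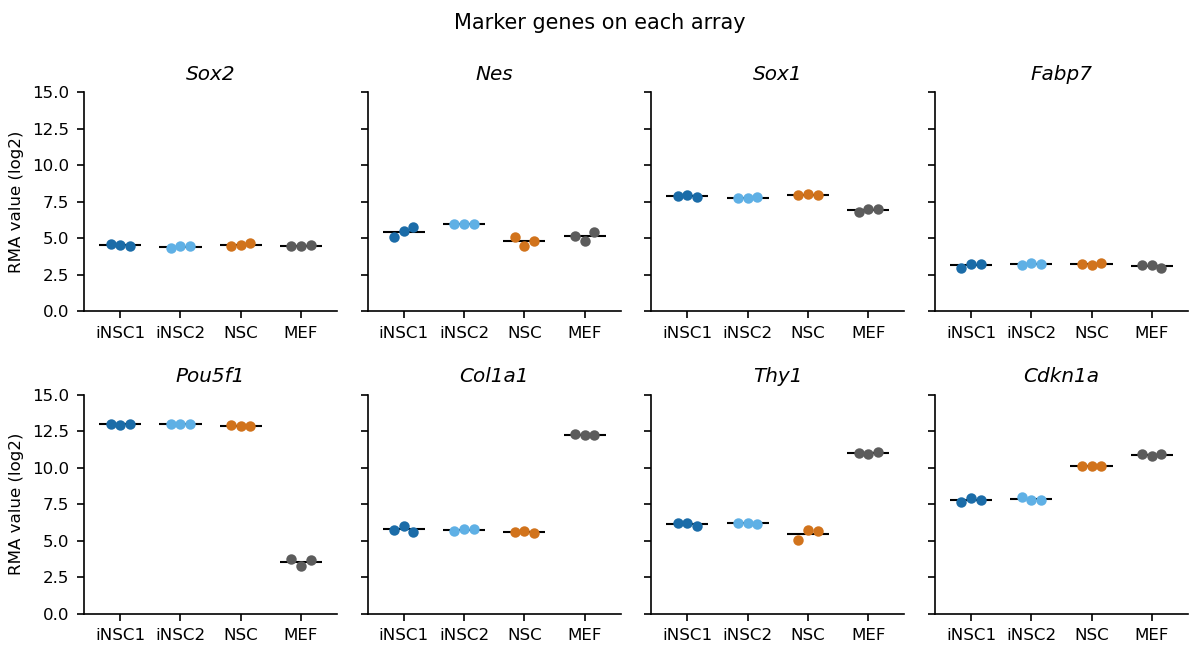
RMA values (log2, vertical axis) of 8 marker genes on each of the 12 arrays; points are arrays and lines are group means (n = 3). Sox2 lay between 4.42 and 4.58 in all group means, whereas Pou5f1 read 12.89 to 13.01 in the iNSC-labelled and NSC-labelled groups and 3.55 in MEF.

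The NSC-labelled and MEF arrays, the reference difference of the study, differed in fibroblast, serum response and cell cycle genes, the last at an adjusted p = 0.0542 with an estimated correlation, which does not pass. In the NSC-labelled arrays 1492 genes were at least 2-fold higher and 1703 at least 2-fold lower than in MEF, of 17103 tested; 938 of these 3195 genes differed at least 4-fold and 142 at least 16-fold. Bgn, the matrix proteoglycan biglycan, fell by 8.50 ± 0.10 (SE, n = 3 and 3 arrays) and Thbs1, the matrix glycoprotein thrombospondin, fell by 8.37 ± 0.10. Pou5f1 rose by 9.34 ± 0.091 and Nr0b1, an orphan nuclear receptor of embryonic stem cells and the adrenal and gonad, by 7.00 ± 0.14. Every array of one group lay apart from every array of the other for each of these genes, as the rule for naming requires. The marker genes of neural stem cells were mixed as described. The arrays carry no detection call, so a low reading can be background and a difference from it is one of readings, not of transcript numbers.

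Fibroblast and mesenchyme genes fell together: 25 of 27 measured members were lower in the NSC-labelled arrays, 25 also when adjusted over the list alone (camera adjusted p = 1.23e-20; adjusted p = 0.0013 with an estimated correlation). Lox, which cross-links collagen, fell by 7.30 ± 0.18, Col1a2 fell by 6.84 ± 0.11, and Loxl1, a relative of Lox, fell by 5.71 ± 0.14 (SE). Serum response and YAP target genes were lower in 18 of 20 members, 18 adjusted over the list alone (camera adjusted p = 3.35e-20; adjusted p = 0.0013 with an estimated correlation). Among them were Acta2, smooth muscle actin (-7.96 ± 0.16), and Tagln, an actin-binding protein (-7.41 ± 0.17). Of the other large falls, Timp2, a metalloproteinase inhibitor, changed by -7.61 ± 0.10, Tnc, the matrix protein tenascin, by -7.49 ± 0.12, and Igfbp7, a binding protein of insulin-like growth factors, by -6.89 ± 0.13. Macrophage and immune genes were lower in 9 of 16 members, 9 adjusted over the list alone (camera adjusted p = 2.4e-06; adjusted p = 0.0347 with an estimated correlation). Markers of another cell type thus moved with the fibroblast genes. Lyz2, lysozyme of myeloid cells, read 8.89 ± 0.76 in MEF and 2.42 ± 0.20 in NSC (SD, n = 3), and the complement subunit genes C1qb, C1qc and C1qa differed by -4.64, -4.32 and -3.98. Laptm5, a lysosomal protein of blood cells named after its value was seen, was the 1 member that was higher (1.36).

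Cell cycle genes were higher in 23 of 25 members of their list, 23 adjusted over the list alone (camera adjusted p = 9.05e-15), but the call was lost at an adjusted p = 0.0542 with an estimated correlation. Ccnb1 and Ccna2, cyclins of mitosis and S phase, rose by 2.95 ± 0.14 and 2.85 ± 0.14, Top2a, a DNA topoisomerase, by 2.79 ± 0.19, and Plk1, a mitotic kinase, by 2.69 ± 0.082 (SE). Pluripotency genes were higher in 4 of 16 members, 4 adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.0868 with an estimated correlation). Besides Pou5f1 and Nr0b1 these were Sall4, a zinc-finger factor of pluripotent cells (2.73 ± 0.12), and Fgf4, a growth factor secreted by them (2.60 ± 0.12). Other large rises were Fetub, a secreted protease inhibitor (6.24 ± 0.22), Gpx6, a glutathione peroxidase (5.70 ± 0.12), Enpp3, an ectonucleotidase (5.53 ± 0.12), Mpzl2, an adhesion molecule (5.37 ± 0.094), Slc38a5, an amino acid transporter (5.09 ± 0.11), and Gna14, a G protein subunit (5.04 ± 0.10).

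Imprinted genes were lower in 14 and higher in 2 of 22 members, 14 and 2 adjusted over the list alone (camera adjusted p = 1.24e-05; adjusted p = 0.0061 with an estimated correlation). H19, a non-coding RNA of the Igf2 locus, fell by 5.86 ± 0.11, Igf2 itself by 3.12 ± 0.14 and Sgce, a sarcoglycan, by 2.95 ± 0.13 (SE). The 2 members that were higher, Mest (1.67) and Peg3 (1.53), were named after their values were seen. Immediate early and stress genes were lower in 7 of 17, 7 adjusted over the list alone (camera adjusted p = 4.48e-06; adjusted p = 0.0061 with an estimated correlation). Dusp1, a phosphatase of MAP kinases, changed by -2.84 ± 0.080 and Trib3, a pseudokinase of the stress response, by -2.26 ± 0.11. HOX genes, which set position along the body axis, were lower in 10 of 36 and higher in 1, Hoxc11, named after its value was seen (1.12). The counts were 10 and 1 adjusted over the list alone (camera adjusted p = 0.0104; adjusted p = 0.276 with an estimated correlation). Hoxa11 changed by -2.25 ± 0.14 and Hoxc8 by -2.05 ± 0.14 (SE).

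Of 21 neural stem cell genes measured, 2 were higher (Sox1 and Pax6) and 2 lower (Cdh2 and Sox9) in the NSC-labelled arrays, the same counts adjusted over the list alone (camera adjusted p = 0.747). Cdh2, N-cadherin, changed by -2.32 ± 0.13 and Sox9, a glial and cartilage transcription factor, by -1.39 ± 0.12 (SE). Astrocyte genes were higher in 5 and lower in 1 of 17 (camera adjusted p = 0.24), with a median of -0.0040 and a mean of 0.74 that differ in sign. Aldoc, the brain form of aldolase, read 4.96 ± 0.079 higher and Acsbg1, an acyl-CoA synthetase of brain, 4.88 ± 0.13 higher. The p53 and Cdkn list held 1 higher and 5 lower of 20 (camera adjusted p = 0.0864), from Cdkn2b at -3.27 ± 0.084 to Cdkn1b at 2.23 ± 0.11, both inhibitors of cyclin-dependent kinases. No other list passed: adjusted p lay at 0.205 for the cholesterol, endothelial and sex-linked lists, 0.222 for epithelial, 0.24 for interferon, 0.422 for oligodendrocyte and neuron, 0.499 for forebrain, 0.722 for midbrain and hindbrain, 0.881 for ependymal, 0.944 for muscle and 0.958 for neural crest genes. In the ependymal and neural crest lists the medians (0.024 and 0.085) and means (-0.14 and -0.12) differed in sign. Of the 5 sex-linked genes, 3 were called higher in the NSC-labelled arrays, the Y-linked Eif2s3y, Ddx3y and Uty. Across the NSC-labelled arrays they read 3.616 to 4.269, 4.574 to 5.018 and 2.734 to 3.458. Across the MEF arrays they read 2.313 to 2.908, 3.426 to 3.712 and 1.973 to 2.158. The call of Uty ended without NSC replicate 3 (0.87). Such low readings can be background, and the sex of the cells was not otherwise tested.

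The comparison of the iNSC-labelled with the MEF arrays asks what separates the induced cells from fibroblasts. The iNSC-labelled arrays had 1405 genes at least 2-fold higher and 1857 at least 2-fold lower than MEF; 994 of these 3262 genes differed at least 4-fold and 145 at least 16-fold. Pou5f1 rose by 9.45 ± 0.079 (SE, n = 6 and 3 arrays) and Atp2a3, a calcium pump of the endoplasmic reticulum, by 6.05 ± 0.072. Thbs1 fell by 8.49 ± 0.087 and Acta2 fell by 8.46 ± 0.14. The neural stem cell markers showed no clear shift with the label here: Sox2 differed by -0.011 (95% confidence interval -0.21 to 0.19). Of the 21 neural stem cell genes, 3 were lower, also 3 adjusted over the list alone: Cdh2 (-3.51 ± 0.11), Notch1, a receptor of cell fate choice (-1.11 ± 0.084), and Sox9 (-1.05 ± 0.11), whose call ended without MEF replicate 1 (-0.97) and with the replicate number as a block (-0.996). The list as a whole did not pass (camera adjusted p = 0.871), with a median of 0.15 and a mean of -0.051 that differ in sign. limma called 0 of its members higher under the rule with the 2-fold minimum. At an unadjusted p under 0.05 and no fold minimum, 10 were higher and 5 lower.

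Fibroblast and mesenchyme genes fell in 25 of 27, 25 adjusted over the list alone (camera adjusted p = 4.45e-17; adjusted p = 0.00267 with an estimated correlation). Lox changed by -7.13 ± 0.16, Col1a2 by -6.73 ± 0.095 and Col1a1 by -6.48 ± 0.087 (SE). Dcn, the proteoglycan decorin, named after its value was seen, was the 1 member that rose (1.86). Serum response and YAP targets were lower in 18 of 20, 18 adjusted over the list alone (camera adjusted p = 4.45e-17; adjusted p = 0.00267 with an estimated correlation). Tagln changed by -7.22 ± 0.15. Macrophage and immune genes were lower in 10 of 16, 10 adjusted over the list alone (camera adjusted p = 1.84e-08; adjusted p = 0.0191 with an estimated correlation). Markers of another cell type thus moved with the fibroblast genes again. Lyz2 changed by -6.47 ± 0.21 and C1qc by -4.37 ± 0.13. Penk, the enkephalin precursor, changed by -6.90 ± 0.15, Csf1, the growth factor of macrophages, by -6.83 ± 0.15, and Tnc by -7.46 ± 0.10.

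Cell cycle genes were higher in 24 of 25, 24 adjusted over the list alone (camera adjusted p = 8.67e-15; adjusted p = 0.0463 with an estimated correlation). Plk1 rose by 3.27 ± 0.071, Ccna2 by 2.89 ± 0.12, Cdc20, an activator of the anaphase-promoting complex, by 2.77 ± 0.082, and Mcm6, part of the replicative helicase, by 2.76 ± 0.092 (SE). Targets of p53 and Cdkn genes fell in 13 of 20, 13 adjusted over the list alone (camera adjusted p = 3.13e-09; adjusted p = 0.0191 with an estimated correlation). Ccng1, a cyclin induced by p53, changed by -4.66 ± 0.21, Trp53inp1, a stress-induced partner of p53, by -3.14 ± 0.18, Cdkn2b by -3.14 ± 0.073, and Cdkn1a, the p21 inhibitor, by -3.06 ± 0.071. Pluripotency genes rose in 6 of 16, 6 adjusted over the list alone (camera adjusted p = 0.0022; adjusted p = 0.0255 with an estimated correlation). After Pou5f1 the largest were Gdf3, a growth factor of pluripotent cells (4.43 ± 0.11), Utf1, a chromatin protein of pluripotent cells (3.70 ± 0.13), and Nr0b1 (2.57 ± 0.12).

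Imprinted genes were lower in 11 and higher in 3 of 22, 11 and 3 adjusted over the list alone (camera adjusted p = 0.00275; adjusted p = 0.0255 with an estimated correlation). H19 changed by -6.97 ± 0.094, Sgce by -3.02 ± 0.12 and Ndn by -2.94 ± 0.073, whereas Phlda2, a growth regulator of the placenta, rose by 4.44 ± 0.12. HOX genes were lower in 14 and higher in 1 of 36, 14 and 1 adjusted over the list alone (camera adjusted p = 0.000158; adjusted p = 0.0705 with an estimated correlation). Hoxc10 changed by -2.68 ± 0.13 and Hoxc6 by -2.65 ± 0.15. The member that rose, Hoxc4, was named after its value was seen (1.18). Immediate early and stress genes were lower in 7 and higher in 2 of 17, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0116; adjusted p = 0.061 with an estimated correlation). Dusp1 changed by -2.92 ± 0.070 and Egr1, a transcription factor induced by growth factors, by -2.23 ± 0.11. Interferon response genes were lower in 4 and higher in 1 of 18, 4 and 1 adjusted over the list alone (camera adjusted p = 0.0385; adjusted p = 0.0755 with an estimated correlation). Ddx58, the RNA sensor RIG-I, rose by 2.99 ± 0.12 and Tap1, a peptide transporter of antigen presentation, fell by 2.83 ± 0.16. Neuron genes rose in 3 of 19, 3 adjusted over the list alone (camera adjusted p = 0.0103; adjusted p = 0.0705 with an estimated correlation). Stmn2, a microtubule regulator, rose by 5.08 ± 0.065, Th, which makes dopamine precursors, by 1.47 ± 0.11, and Map2, a microtubule-binding protein, by 1.35 ± 0.13.

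Epithelial genes were higher in 4 of 16, 4 adjusted over the list alone (camera adjusted p = 0.0331; adjusted p = 0.185 with an estimated correlation). They were the keratins Krt19 (3.82 ± 0.082), Krt14 (2.53 ± 0.093) and Krt8 (1.35 ± 0.094) and the epithelial transcription factor Elf3 (1.09 ± 0.10). Among the largest rises outside the lists were Krtdap, a protein of differentiating keratinocytes (5.58 ± 0.11), Lgals7, a galectin of stratified epithelium (5.08 ± 0.099), and Aqp3, a water and glycerol channel (5.202 ± 0.12). Cyp4f39 and Cyp2s1, cytochromes P450, rose by 5.95 ± 0.11 and 5.32 ± 0.17, Gng3, a G protein subunit of neurons, by 5.19 ± 0.13, and Ret, the receptor tyrosine kinase for GDNF ligands, by 5.18 ± 0.15. The remaining lists did not pass: adjusted p was 0.179 for cholesterol, 0.374 for endothelial, 0.699 for forebrain, astrocyte and sex-linked, 0.773 for neural crest, 0.906 for oligodendrocyte, and 0.952 for midbrain and hindbrain, muscle and ependymal genes. Medians and means differed in sign for the muscle list (0.099 and -0.034) and the ependymal list (0.056 and -0.14). Members called in those lists included Dhcr7, of cholesterol synthesis (3.25 ± 0.059), and Ngfr, a neurotrophin receptor (3.31 ± 0.10). Of 5 sex-linked genes 1 was called, Xist, at 4.62 to 5.547 across the iNSC-labelled and 3.632 to 4.031 across the MEF arrays.

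The comparison of iNSC-labelled with NSC-labelled arrays asks how the induced cells differ from the cells that, per the protocols, were kept in the same medium. In the iNSC-labelled arrays 497 genes were at least 2-fold higher and 624 at least 2-fold lower; 293 of these 1121 genes differed at least 4-fold and 31 at least 16-fold. Ret rose by 5.56 ± 0.15 (SE, n = 6 and 3 arrays) and Timp3, a metalloproteinase inhibitor bound to matrix, by 5.44 ± 0.11. Adam23, a surface protein of the nervous system, fell by 5.196 ± 0.15 and Acsbg1 fell by 4.98 ± 0.12. Every iNSC-labelled array lay apart from every NSC-labelled array for these genes, as the rule for naming them requires. Of the 21 neural stem cell markers, 1 was called between these groups, Cdh2 (-1.19).

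Cdkn inhibitors and p53 targets had the smallest list p of this comparison. Of 20 members 10 fell, 10 also when adjusted over the list alone, and the others did not pass (camera adjusted p = 1.22e-10; adjusted p = 0.032 with an estimated correlation). Ccng1 read 4.75 ± 0.40 in iNSC1 and 4.85 ± 0.25 in iNSC2 against 8.86 ± 0.28 in NSC (SD, n = 3 each), a difference of -4.06 ± 0.21 (SE). Trp53inp1 changed by -3.91 ± 0.18, Cdkn1a by -2.28 ± 0.071, and Zmat3, an RNA-binding protein induced by p53, by -1.92 ± 0.088. limma called 0 of 25 cell cycle genes, also 0 adjusted over the list alone, with 8 higher and 7 lower at an unadjusted p under 0.05 and a list median of 0.056 (camera adjusted p = 0.356).

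**Figure D2:**
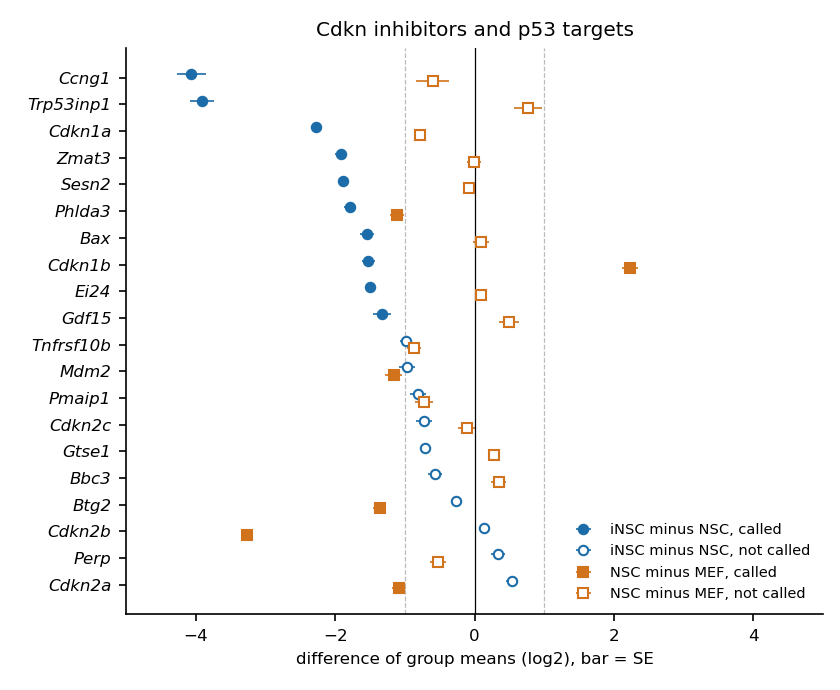
Difference of group means (log2, horizontal axis; bars are SE) for the 20 measured Cdkn inhibitors and p53 targets, iNSC minus NSC in blue circles and NSC minus MEF in orange squares; filled symbols are calls. Of the 20 genes, 10 were called lower in iNSC minus NSC, against 5 lower and 1 higher in NSC minus MEF.

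Astrocyte genes were lower in 6 and higher in 1 of 17, 6 and 1 adjusted over the list alone (camera adjusted p = 0.00309), and the call was lost at an adjusted p = 0.0504 with an estimated correlation. After Acsbg1 the largest changes were in Ndrg2, a cytoplasmic protein of astrocytes (-2.45 ± 0.091), Id3, an inhibitor of helix-loop-helix factors (-2.38 ± 0.13), and Fgfr3, a receptor of fibroblast growth factors (2.16 ± 0.11). Neuron genes were higher in 3 of 19, 3 adjusted over the list alone (camera adjusted p = 0.0166; adjusted p = 0.165 with an estimated correlation). Tubb3, a neuronal tubulin, rose by 2.62 ± 0.093, Map2 by 1.19 ± 0.13 and Stmn2 by 1.18 ± 0.065. Serum response and YAP targets were higher in 5 of 20, 5 adjusted over the list alone (camera adjusted p = 0.0491; adjusted p = 0.287 with an estimated correlation). The largest were Ccn1, a matrix signalling protein also called Cyr61 (1.81 ± 0.069), and Zyx, a focal adhesion protein (1.18 ± 0.090).

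Imprinted genes went both ways, with 6 higher and 3 lower of 22, 6 and 3 adjusted over the list alone. The list did not pass (camera adjusted p = 0.288), and its median (-0.025) and mean (0.46) differ in sign. Phlda2 rose by 4.16 ± 0.12, Cdkn1c, a Cdk inhibitor, by 3.42 ± 0.095, and Slc38a4, an amino acid transporter, by 3.17 ± 0.12, whereas Peg3, a zinc-finger protein, fell by 2.87 ± 0.15. Krt17, a keratin, rose by 4.94 ± 0.084, Krt19 by 2.38 ± 0.082, Krt14 by 2.24 ± 0.093 and Krt8 by 1.43 ± 0.094, while Krt20, named after its value was seen, changed by -1.60. The Gene Ontology term keratinization, tested after the data had been seen, did not pass among the higher genes (4 genes against 0.627 expected; adjusted p = 0.131). The epithelial list had 3 of 16 called, Krt19, Krt14 and Krt8, and did not pass (camera adjusted p = 0.195). Of 5 sex-linked genes, Xist, the RNA that coats the inactive X chromosome, read 2.33 ± 0.20 higher, and the Y-linked genes Eif2s3y, Ddx3y and Uty read -2.02 ± 0.15, -1.63 ± 0.12 and -1.34 ± 0.13 (camera adjusted p = 0.0618). Xist group means were 5.25 in iNSC1, 5.19 in iNSC2, 2.90 in NSC and 3.85 in MEF. Across the NSC-labelled arrays Eif2s3y read 3.616 to 4.269, Ddx3y 4.574 to 5.018 and Uty 2.734 to 3.458. Across the iNSC-labelled arrays they read 1.665 to 2.125, 2.87 to 3.458 and 1.604 to 1.984. Such low readings can be background. Xist was called higher and these 3 Y-linked genes lower, with every iNSC-labelled array apart from every NSC-labelled array. The list test asks for a shift of all members in 1 direction. Xist and the Y-linked genes went opposite ways, so its p cannot decide on the sex of the cells. No other test of sex was run, so a difference in sex between the groups stays open for the calls of this comparison. Pluripotency genes were higher in 2 and lower in 1 of 16 (camera adjusted p = 0.448). Gdf3 changed by 3.93 ± 0.11, Utf1 by 3.19 ± 0.13 and Nr0b1 by -4.44 ± 0.12, while Pou5f1 differed by 0.11 (95% confidence interval -0.061 to 0.27).

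Further large rises were Cyp4f39 (5.38 ± 0.11), Plac8, a protein named after placenta (5.17 ± 0.11), Car14, a carbonic anhydrase (4.92 ± 0.082), Lypd5, a membrane-anchored surface protein (4.75 ± 0.11), Dcn (4.74 ± 0.14), Aqp3 (4.71 ± 0.12) and Crabp2, a carrier of retinoic acid (4.54 ± 0.079). Further large falls were Srgn, a granule proteoglycan of blood cells (-4.90 ± 0.14), Alox15, a lipoxygenase (-4.78 ± 0.17), Gpx6 (-4.59 ± 0.11), Foxd1, a forkhead transcription factor (-4.53 ± 0.12), Enpp1, which makes pyrophosphate (-4.52 ± 0.12), Tspan12, a tetraspanin of Wnt signalling (-4.43 ± 0.17), and Il34, a ligand of the Csf1 receptor (-4.35 ± 0.13). Nes read 0.94 ± 0.15 higher in the iNSC-labelled arrays, under the 2-fold bound, and passed it without iNSC1 replicate 1 (1.03), without NSC replicate 1 (1.08) and after quantile normalisation (1.00). Fibroblast genes had 1 higher (Dcn) and 1 lower (Fstl1, -1.91 ± 0.11) of 27, and HOX genes 1 higher (Hoxc4, 2.45 ± 0.16) and 5 lower of 36, among them Hoxc10 (-3.00 ± 0.13). Both lists had a camera adjusted p = 0.195, as did neural crest and interferon genes. Adjusted p was 0.0988 for forebrain, 0.138 for immediate early, 0.288 for oligodendrocyte, 0.378 for cholesterol, 0.431 for midbrain and hindbrain, 0.464 for neural stem cell, 0.655 for endothelial, 0.677 for macrophage, 0.858 for muscle and 0.955 for ependymal genes. Medians and means differed in sign for macrophage (0.026 and -0.23), endothelial (0.038 and -0.18) and muscle genes (0.067 and -0.088). List by list, the counts adjusted over the list alone equalled those over all genes.

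Taking each induced set on its own, iNSC1 had 1457 genes higher and 1925 lower than MEF, and iNSC2 1392 and 1806. Against the NSC-labelled arrays, iNSC1 had 492 higher and 661 lower, and iNSC2 527 and 610.

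The position of the iNSC-labelled arrays was then set against the reference difference between NSC-labelled and MEF arrays. Over the 3195 genes called in that reference, the iNSC minus MEF difference followed the NSC minus MEF difference with a slope of 0.849 through 0, and 94.7% of the genes differed in the same direction. Across these genes Pearson's r was 0.8997 and Spearman's rho 0.876; genes are not independent replicates, so no p is given. Single iNSC-labelled arrays had slopes from 0.826 (iNSC2 replicate 3) to 0.866 (iNSC1 replicate 3). Both differences subtract the same MEF arrays. Over all genes the slope was 0.848 and r 0.829, where simulated groups without any change gave 0.5002 and 0.578. The covariance was 0.815 against a simulated 0.00880, a difference of 0.807, and 80.2% of genes had the same sign against a simulated 69.6%. The simulation shares the MEF arrays in the same way, so the simulated covariance of 0.00880 argues against array noise as the source of the excess. The simulated groups do not differ from MEF, whereas both labelled groups do. The values thus do not separate likeness to the NSC-labelled arrays from a shared difference from MEF. No version that takes separate MEF arrays for each difference was run.

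Of the 3195 genes, 2027 (63.4%) were called in iNSC minus MEF in the same direction and not in iNSC minus NSC, and are termed NSC-like here by label only. Another 347 (10.9%) were called against NSC but not against MEF (MEF-like), 94 lay between both groups, 145 lay beyond the NSC-labelled mean or on the other side of MEF, and 582 were not resolved. Among genes lower in NSC than in MEF, 1236 of 1703 (72.6%) were NSC-like, and among genes higher in NSC, 791 of 1492 (53.02%). MEF-like genes numbered 243 of the 1492 that were higher and 104 of the 1703 that were lower. The first class held Pou5f1, Thbs1, Acta2, Tnc, Lox and Col1a1. The MEF-like class held Acsbg1, Alox15, Foxd1, Tspan12 and Plac8, whose iNSC minus MEF differences ran from -0.76 for Tspan12 to 0.69 for Plac8. Crabp2 and Dcn were lower in NSC than in MEF (-3.38 and -2.88) and higher in iNSC than in MEF (1.15 and 1.86). A further 381 genes were called against both MEF and NSC without being called between those, 231 higher and 150 lower in the iNSC-labelled arrays. Genes higher in both iNSC minus MEF and NSC minus MEF numbered 854, against 123 for independent calls, and genes lower in both 1381, against 185. The shared MEF arrays raise such overlaps. Genes higher in iNSC than NSC and lower in NSC than MEF numbered 180 (49.5 if independent), and the opposite 292 (54.4 if independent). These comparisons share the NSC-labelled arrays, so independence is not what unchanged groups would give. Over all genes, iNSC minus NSC and MEF minus NSC had an r of 0.259 against a simulated 0.578, and a covariance of 0.147 against 0.00879, a difference of 0.138.

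**Figure D3:**
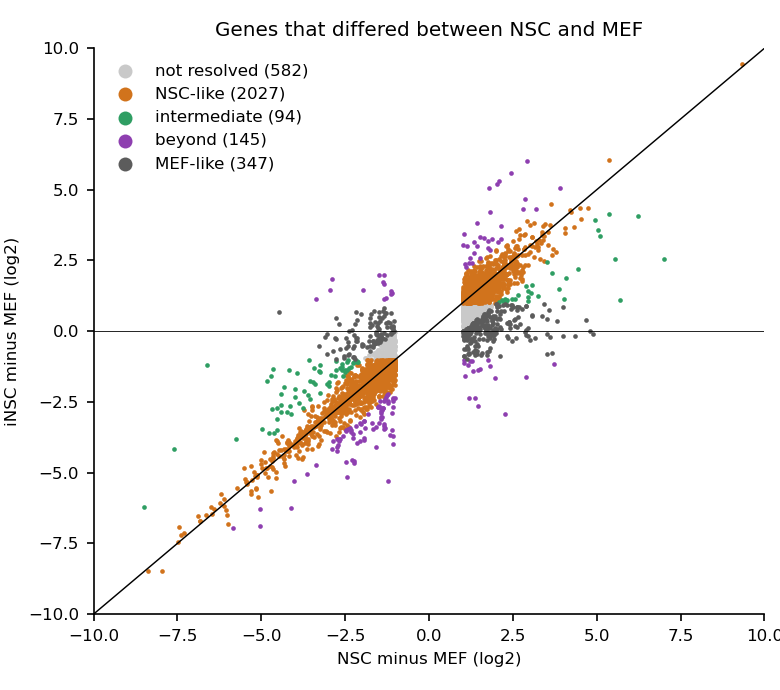
Differences of group means (log2) for the 3195 genes called in NSC minus MEF: NSC minus MEF on the horizontal and iNSC minus MEF on the vertical axis, coloured by class; the diagonal marks equal differences. The 2027 NSC-like genes lie along the diagonal and the 347 MEF-like genes near the horizontal line at 0.

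By root mean square log2 difference over all 17103 genes, the 6 iNSC-labelled arrays lay at a median of 0.604 from the NSC-labelled mean (0.591 to 0.613) and 1.02 from the MEF mean (0.999 to 1.03). The ratio of these distances was 0.593 ± 0.011 (mean ± SD, n = 6 arrays). Group means were 0.186 apart for iNSC1 and iNSC2, 0.588 for iNSC1 and NSC, 0.586 for iNSC2 and NSC, and 0.981 for NSC and MEF.

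**Figure D4:**
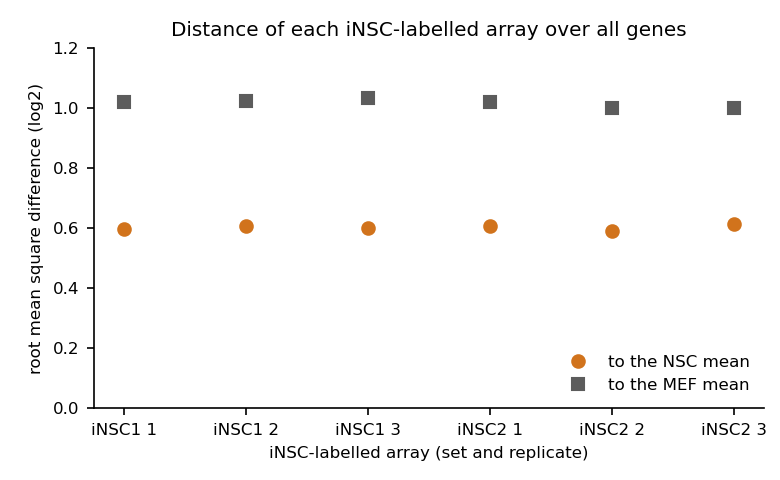
Root mean square difference (log2, vertical axis) over 17103 genes of each of the 6 iNSC-labelled arrays to the NSC-labelled mean (circles) and to the MEF mean (squares). All 6 arrays lie between 0.591 and 0.613 from the NSC-labelled mean and between 0.999 and 1.03 from the MEF mean.

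The 2 induced sets, iNSC1 and iNSC2, differed little. Of 17103 genes 26 were called, 15 higher and 11 lower in iNSC1, and 2 of them differed at least 4-fold. Smpd3, a neutral sphingomyelinase, read 7.84 ± 0.076 in iNSC1 and 5.40 ± 0.042 in iNSC2 (SD, n = 3 each), a difference of 2.45 ± 0.12 (SE; adjusted p = 7.22e-09). Utf1 read 9.25 ± 0.12 and 6.87 ± 0.089, a difference of 2.38 ± 0.15 (adjusted p = 8.51e-08), with means of 4.87 in NSC and 4.35 in MEF. Of the 21 neural stem cell markers limma called 0, with 1 higher and 3 lower at an unadjusted p under 0.05 (camera adjusted p = 0.509). Sox2 differed by 0.15 (95% confidence interval -0.084 to 0.38) and Nes by -0.56 (-0.93 to -0.18; adjusted p = 0.142), with no overlap between the sets for Nes.

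Higher in iNSC1 were also Bex1, a brain-expressed X-linked protein (1.42 ± 0.16), Esrp2, an epithelial splicing regulator (1.34 ± 0.10), Tgm2, a transglutaminase (1.18 ± 0.11), Exoc3l, of the exocyst family (1.16 ± 0.11), Slc43a1, an amino acid transporter (1.15 ± 0.13), and Car7, a carbonic anhydrase (1.08 ± 0.14). Lower in iNSC1 were Susd2, a membrane protein (-1.27 ± 0.12), Lpar3, a receptor of lysophosphatidic acid (-1.15 ± 0.12), Bgn (-1.15 ± 0.10), Rtl1, an imprinted gene derived from a retrotransposon (-1.14 ± 0.11), Nrn1, the neurite growth protein neuritin (-1.12 ± 0.093), and Epb41l4a, a cytoskeletal protein (-1.10 ± 0.14). Krt8 was 1.04 ± 0.11 higher, a call that ended without iNSC1 replicate 2 (0.98) and without iNSC2 replicate 2 (0.98). The count of 11 lower genes moved to 7 without iNSC2 replicate 1, to 20 without iNSC2 replicate 3 and to 17 with arrays centred on their median. Camera passed 5 lists: serum response and YAP targets were lower (adjusted p = 0.000788, median -0.16) as were fibroblast genes (0.0218), and cell cycle (0.0187), epithelial (0.0218) and macrophage genes (0.0265) were higher. None of the 5 calls held with an estimated correlation: adjusted p = 0.28 for serum response, 0.304 for fibroblast and epithelial, 0.626 for cell cycle and 0.341 for macrophage genes. The other lists did not pass; imprinted genes had a median of -0.0052 and a mean of 0.037. Only Utf1 and Krt8 were called among the members of the 23 lists.

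Set beside the ratios and p-values in the authors' table, counts at the same thresholds were 1404 higher and 1858 lower for iNSC minus MEF (3261 of 3262 calls shared) and 1492 and 1703 for NSC minus MEF (3195 of 3195 shared). For iNSC minus NSC all 1121 calls were shared. For iNSC1 against iNSC2, 24 of the 26 genes called here had an authors' adjusted p under the same threshold. By adjusted p alone, the authors' table has 147 genes in that comparison, against 393 here.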

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

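The tests of probe pairing, exchanged labels, other cells and pluripotent cells, and those of Trp53 and of the cell cycle list, were chosen after the results they measure were seen; the germ line, second p53 and second macrophage lists were written after the main results and before their own values.

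The change against MEF or NSC differed between iNSC1 and iNSC2 for 26 genes, by the test of iNSC1 minus iNSC2 itself. Utf1 (2.38), Krt8 (1.04) and Bgn (-1.15) are among them, and the call of Krt8 ended without iNSC1 replicate 2 (0.98) and without iNSC2 replicate 2 (0.98). The other splits were too few for a share under 0.05: 1 of 10 splits called as many genes, with 27 genes in the real split fitted on these 6 arrays and at most 0 in the others. For NSC minus MEF the splits were also too few (1 of 10; 3194 genes against at most 0). For iNSC minus MEF, 1 of 84 splits called as many genes (3261 against at most 3). For iNSC minus NSC it was also 1 of 84 (1121 against at most 7). The other splits mix arrays of groups that differ, which widens the spread within their groups. The labels do not say whether arrays are separate cultures, so the splits cannot exclude chance differences between cultures.

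Differences past the same thresholds appeared in probe sets that no comparison of the report uses. Of 1452 probe sets with several gene symbols, 227 passed in iNSC minus MEF, 59 in iNSC minus NSC and 240 in NSC minus MEF. Of 1919 with no symbol, 119, 37 and 163 passed, and of the 7041 left out of the second table, 7, 1 and 16.

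Most neural stem cell markers were not called higher in the NSC-labelled arrays: 2 of 21, Sox1 and Pax6, were called higher than in MEF (8 higher and 5 lower at an unadjusted p under 0.05), and the call of Sox1 ended without MEF replicate 1 (0.94). The tables argue against probe sets paired with wrong genes, since 25 of 27 fibroblast markers were lower as the MEF label predicts. The same count argues against exchanged NSC and MEF labels. The neural stem cell markers cannot decide on an exchange, since 2 were called higher in each group (Cdh2 and Sox9 in MEF). For a pluripotent stem cell population the values go both ways: 4 of 16 markers were called higher (7 higher and 1 lower at an unadjusted p under 0.05; camera adjusted p = 0.0325; adjusted p = 0.0868 with an estimated correlation), as were Tdh (4.53) and Fbxo15 (3.69), chosen after their values were seen, whereas Lin28a (0.054), Dppa4 (0.078) and Esrrb (-0.085) were not called. For a germ line population limma called 0 of 15 list members higher, with 2 higher and 3 lower at an unadjusted p under 0.05. Arrays made from cells other than neural stem cells, pluripotent ones included, may account for the pattern, but the 2 markers called higher only restate it, and no test here decides it.

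Of 20 Cdkn inhibitors and p53 targets, 10 were lower in the iNSC-labelled than in the NSC-labelled arrays, 1 of them Cdkn1b, a Cdk inhibitor not known as a p53 target; Cdkn1c, a Cdk inhibitor outside the list, rose by 3.42. The tables argue against lower Trp53 mRNA as the cause (0.16 on the log2 scale in iNSC minus NSC). The cell cycle list had a median of 0.056, with 8 genes higher and 7 lower at an unadjusted p under 0.05. This argues against fewer or more dividing cells only as far as these mRNAs follow division. The share of dividing cells was not measured. In a second list of p53 targets the median was -0.72, 17 of 19 were negative and 8 were called lower (camera p = 2.84e-08; p = 0.00118 with an estimated correlation). Lower p53 activity may therefore be a candidate explanation, as a hypothesis found and tested on the same arrays. Neither p53 protein nor its modification was measured, and a mutation of the gene stays open.

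Macrophage genes were higher in the MEF arrays, with Lyz2 at 8.89, C1qa at 8.29, C1qb at 8.22 and C1qc at 7.94 in their means. In a second list of macrophage genes 5 of 13 were called higher in MEF than in NSC-labelled arrays (C3ar1, Cd53, Ctss, Itgb2 and Pld4; camera p = 3.26e-05; p = 0.0169 with an estimated correlation), with 11 higher in MEF and 1 lower at an unadjusted p under 0.05. Macrophages among the MEF cells may explain this, and so may expression of single immune genes by the fibroblasts. With 5 of 13 the list does not decide, so these explanations cannot be told apart here. The labels name no sort that would remove such cells.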

How the results depend on the processing

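The alternatives for the gene classes and for each iNSC set against MEF and NSC were chosen after seeing the data; the others were planned. With adjusted p alone, without a fold minimum, counts higher and lower were 5003 and 4555 for iNSC minus MEF, 2810 and 3306 for iNSC minus NSC, 4780 and 4092 for NSC minus MEF, 127 and 266 for iNSC1 minus iNSC2, 4713 and 4361 for iNSC1 minus MEF, 4540 and 4229 for iNSC2 minus MEF, 2609 and 3099 for iNSC1 minus NSC, and 2430 and 2750 for iNSC2 minus NSC, as dropping the minimum must raise them. With the filter at 6, fewer genes were tested. The class of each gene called in NSC minus MEF: not resolved then held 349. With the filter 2 lists passed in iNSC minus NSC, against 4 without it. The median distance of iNSC arrays to NSC and to MEF: to NSC was 0.801 with the filter. The median distance of iNSC arrays to NSC and to MEF: to MEF was 1.401. The median distance of iNSC arrays to NSC and to MEF: ratio was 0.574. As 1 minus Pearson the ratio was 0.358, on another scale. Lists passing with an estimated correlation were 7, 1, 5 and 0 in iNSC minus MEF, iNSC minus NSC, NSC minus MEF and iNSC1 minus iNSC2, and with fry 19, 19, 18 and 3; fry does not set a list against other genes. The neural stem cell list in iNSC minus MEF (fry adjusted p = 0.0337) and the astrocyte list (4.12e-05) turned direction with fry, and the cause was not tested. Genes lower in iNSC1 minus iNSC2 numbered 17 with median-centred arrays (the cause was not tested) and 7 to 20 leaving out 1 array: 7 without iNSC2 replicate 1 and 20 without iNSC2 replicate 3, with fewer arrays.

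Leaving out 1 array, counts higher and lower ranged from 1365 to 1449 and 1765 to 1986 in iNSC minus MEF, 495 to 519 and 574 to 693 in iNSC minus NSC, and 1373 to 1573 and 1610 to 1790 in NSC minus MEF. With the replicate number as a block the counts were 1473 and 1985, 497 and 624, and 1530 and 1789. Number 5 occurs only among the MEF arrays, so the block takes up that array. Without MEF replicate 5 and with no block, iNSC minus MEF had 1439 and 1986, and NSC minus MEF 1505 and 1790. Same-number correlations between groups ran from -0.18 to 0.28, with 6 of 15 over 0.1 and 1 under -0.1. They leave open whether the numbers pair some of the arrays. For named genes, 18 changes leaving out 1 array and 4 under other alternatives crossed into a call, 31 and 5 ended one, and none turned direction. For lists, 36 alternatives made a call and 27 ended one. Arrays carry no detection call, so signal over background limits what can be said of genes near the floor.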

Other observations

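The Gene Ontology terms here were chosen after seeing the data, and 522 terms of 10 to 500 genes were tested for each direction of each comparison. Among genes higher in NSC-labelled than in MEF arrays, 22 terms passed, among them cell division (75 genes against 19.7 expected; adjusted p = 1.14e-23), DNA repair (49 against 16.03; 3.04e-11) and RNA splicing (34 against 15.9; 0.000756). Among genes lower there, 18 passed, among them cell adhesion (97 against 40.3; 9.99e-15) and collagen catabolic process (8 against 1.57; 0.00346). In iNSC minus MEF, rRNA processing (23 against 5.61; 1.4e-07) and ribosome biogenesis (20 against 4.49; 2.49e-07) were among 19 terms of the higher genes, and angiogenesis (28 against 11.6; 0.000624) among 26 terms of the lower genes.

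In iNSC minus NSC, 7 terms passed among the higher genes, with axonogenesis (9 genes against 1.64 expected; adjusted p = 0.0151) and microtubule-based process (6 against 0.976; 0.0294). Cell cycle arrest (10 against 1.95; 0.00877) and oxidation reduction (37 against 19.1; 0.0219) were the 2 terms passing among the lower genes. Genes of a term are not independent of one another, and these p-values count genes, not arrays.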
